A study of Mus musculus with 10 samples.

How the data were processed

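Amacrine cells, the mostly inhibitory interneurons of the inner retina, were profiled one by one in 10 libraries from retinas of mice at postnatal day 19. Per the labels' protocols, the mice carried a GFP transgene, the retinas were dissociated with papain, and the cells were stained with antibodies against CD133 and CD73. CD133 is the product of Prom1 and CD73 the product of Nt5e. Per the labels' protocols, the sort kept cells negative for GFP and for both antibodies and positive for Calcein Blue, a dye that marks living cells. As background, rods carry CD73 and photoreceptors express Prom1. Libraries were made on the 10x Genomics Chromium platform with 3′ chemistry, and per the labels' protocols approximately 10000 cells were loaded and approximately 6000 recovered on each channel on average. The labels place 1 library in batch 1, 5 in batch 2 and 4 in batch 3, and give no other group. They do not say whether libraries came from separate animals, so the p-values below measure the spread between libraries, which may be technical.

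The deposited table held counts, that is, whole numbers of unique molecular identifiers (UMIs, which count each captured RNA molecule once) per gene and cell. Per the submitters' processing notes, Cell Ranger 2.1.0 and the mouse build mm10 were used; the gene annotation, the filters on cells and any removal of doublets are not given in the sources used here. Every value was checked to be a whole number of at least 0. The table had 27933 gene symbols, of which 7109 had no count, and 32523 cells, each with at least 601 genes, so the planned minimum of 200 genes per cell removed none. Libraries held 950 to 4738 cells, below the approximate number recovered that the protocol states. Gene positions come from GENCODE release M21 of GRCm38, the assembly that mm10 names; 26646 symbols (95.4%) had a gene record there, and coordinates are given only for symbols with a single record. Over genes, the mean chi-square of summed counts per gene between library pairs was 2.52 to 7.11 within batches and 10.4 to 28.6 between batches. It treats UMIs as independent although those of a cell go together, so it cannot tell whether libraries share a suspension. Every library was counted as a replicate.

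The following choices were fixed before the data were examined, except where stated. Counts were scaled to 10000 per cell and log-transformed, and 3000 variable genes were chosen within libraries with scanpy 1.11.5. All genes of 12 fixed lists, Gad1, Gad2, Slc6a9, and mitochondrial, ribosomal, haemoglobin, sex-linked and rod genes were then dropped, which left 2689 features. Values were centred and scaled within each library, capped at 10 and reduced to 50 principal components. Leiden clustering at resolution 3 (leidenalg 0.10.2, 20 neighbours) gave 77 clusters; this number follows from the resolution and is not a count of types. Levels in a cluster are CPM, the summed UMIs of a gene scaled to the total UMIs of the cluster, computed here from the deposited counts. Clusters were named from fixed marker lists, and the numerical rule was set after the clusters had been seen. A cluster was taken as another cell class where at least 4 markers of that class lay at least 2.5 times above all other cells, with a pseudocount of 20 CPM and a level of at least 20 CPM. An amacrine type needed at least 3 markers and 75% of its list at 2-fold, or, for lists of 3 markers, 2 at 2-fold and the third at 1.2-fold. Starburst, catecholaminergic and A17 cells also had to be of the Gad class, and AII and SEG cells of the Slc6a9 class. The classes checked were rods, cones, bipolar cells, ganglion cells, Müller glia, horizontal cells, astrocytes, microglia, endothelium, pericytes and erythrocytes. A set of dissociation stress genes was measured but was not used to set clusters aside. Names are therefore rebuilt here and can differ from the authors' own. A cluster counted as high for Gad1 plus Gad2, or for Slc6a9, above the Otsu threshold over clusters, 546 CPM for the Gad pair and 160 CPM for Slc6a9.

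For genes between transmitter classes, amacrine cells were gated on the transmitter genes alone, whatever their cluster. The Gad gate required at least 2 UMIs of Gad1 or Gad2 and none of Slc6a9, and the Slc6a9 gate the reverse; 11.7% of the gated cells stood exactly at 2 UMIs. Counts were summed per library and class, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, library as a block, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. Each named type was tested in the same way against all other amacrine cells of the same libraries, where a library held at least 10 cells of the type. Genes that had served as clustering features and the type's own markers were left out of those counts. The SE given with a log2 change is its absolute value divided by the square root of the quasi-likelihood F statistic. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Shares of cells were compared between batches 2 and 3 with exact two-sided permutation tests, whose smallest p is 0.0159 at 5 against 4 libraries. The shares of the clusters with Prom1 of at least 200 CPM and of the AII-marked clusters with both transmitter genes were added to that family after the data had been seen. For each neuropeptide that reached 200 CPM in a cluster, the cluster with the highest median over libraries was compared with the second by an exact sign-flip test of paired log2 ratios (pseudocount 10 CPM, at least 5 cells per library and cluster, at least 6 libraries).

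Genes are named by a rule, and not every gene it took is printed. In the class contrast it took the 3 largest changes in each direction per list, and in the type contrasts the 2 largest increases and the largest decrease. These needed an adjusted p under 0.05, a log2 change of at least 1, at least 20 CPM in the higher group and a single direction in every library. It also took the 5 largest of each direction outside the lists, peptides of at least 1000 CPM, the 5 largest of each direction between batches at 20 CPM or more, and Gad1, Gad2, Slc6a9, Slc32a1, Meis2 and Tcf4 in any case. The models were tested on simulated counts drawn from the means, library sizes and dispersions of the real sums. Known log2 changes of 0.5, 1, 2 and 3 were set in about 50 genes each, with no library effect. The real comparisons called far more genes, so the rates below need not hold for them. For the class comparison (11117 genes), 98.0% of genes changed by a log2 of 1 and 78.0% of those changed by 0.5 were recovered. The corresponding shares were 83.7% and 52.0% for the starburst comparison (11134 genes) and 92.0% and 72.9% for the batch comparison (13943 genes). False calls made up 4.59%, 8.29% and 3.74% of the calls of these 3 simulations.

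Doublets were scored per library with scrublet in scanpy at an expected rate of 0.06. It called 25 of 32523 cells (0.0769%), too few for the call to be usable, so an alternative without the 5% of cells with the highest scores in each library was added after the data had been seen. Other alternatives were DESeq2 (1.42.0) and its size factors, no filter on low counts, no library block, gates of 1 and 4 UMIs, classes by cluster, single batches, Leiden resolutions of 1.5 and 5, features that kept the fixed lists, no centring within libraries, a rule on cells with a UMI for the classes, a minimum of 10 cells for the peptides, and estimated correlations or fry for the lists. Libraries were left out in turn from the batch comparison, and, as an addition after the data had been seen, from the differences in shares. Cells of other classes were left out of every comparison except that of their own share between batches.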

Results

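The series profiled amacrine cells of the mouse retina at postnatal day 19 to sort them into molecular types. Amacrine cells release GABA or glycine onto bipolar cells, ganglion cells and each other. The 10 libraries held 32523 cells and 171257947 UMIs, from 6302659 to 26028492 UMIs per library. Median depth per cell ran from 3296.5 UMIs in library 5 to 5717 in library 1. Of 77 clusters, 4 carried markers of bipolar cells or Müller glia and were set aside with their 515 cells (1.58% of all cells), which left 32008 amacrine cells in 73 clusters.

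Most amacrine cells belonged to clusters high for the enzymes that make GABA. Clusters high for Gad1 (chromosome 2, 70553072 to 70602014, plus strand) and Gad2 (chromosome 2, 22622205 to 22693874, plus strand) numbered 46 and held 63.5% ± 7.07 of the amacrine cells (SD, n = 10 libraries). Clusters high for Slc6a9 (chromosome 4, 117834506 to 117875198, plus strand), the glycine transporter GlyT1 that marks glycinergic amacrine cells, numbered 17 and held 32.3% ± 8.36 of the cells. A further 9 clusters were high for both (3.29% ± 1.40), and cluster 44 for neither (0.990% ± 0.373). Under the alternative rule on cells with a UMI, clusters high for neither held 5.16% of the cells. Cluster 44 held 288 cells led by Igfbp7 and Fam19a1, with 352 CPM of Gad1 plus Gad2 and 125 CPM of Slc6a9, each below its threshold. The markers named 3 amacrine types. Starburst-like cells (cluster 17, 633 cells) expressed Chat at 297 CPM, Slc18a3 at 630 CPM and Sox2 at 332 CPM, and made up 1.84% ± 1.07 of the cells. AII-like cells (clusters 3, 29 and 71, 1911 cells), named from Gjd2, Prox1, Dab1 and Nfia, made up 6.02% ± 0.843. Calb2 of the AII list did not meet the 2-fold rule in these clusters, nor did Megf10 of the starburst list in cluster 17. VG3-like cells (cluster 16, 653 cells), with Slc17a8, the vesicular glutamate transporter VGLUT3, at 1149 CPM, made up 2.03% ± 0.335. Cluster 20 had the highest Th, the rate-limiting enzyme of dopamine synthesis, at 209 CPM, but no other marker of its list at the level required, and stayed unnamed. No cluster met the rule for A17 or SEG cells.

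**Figure D1:**
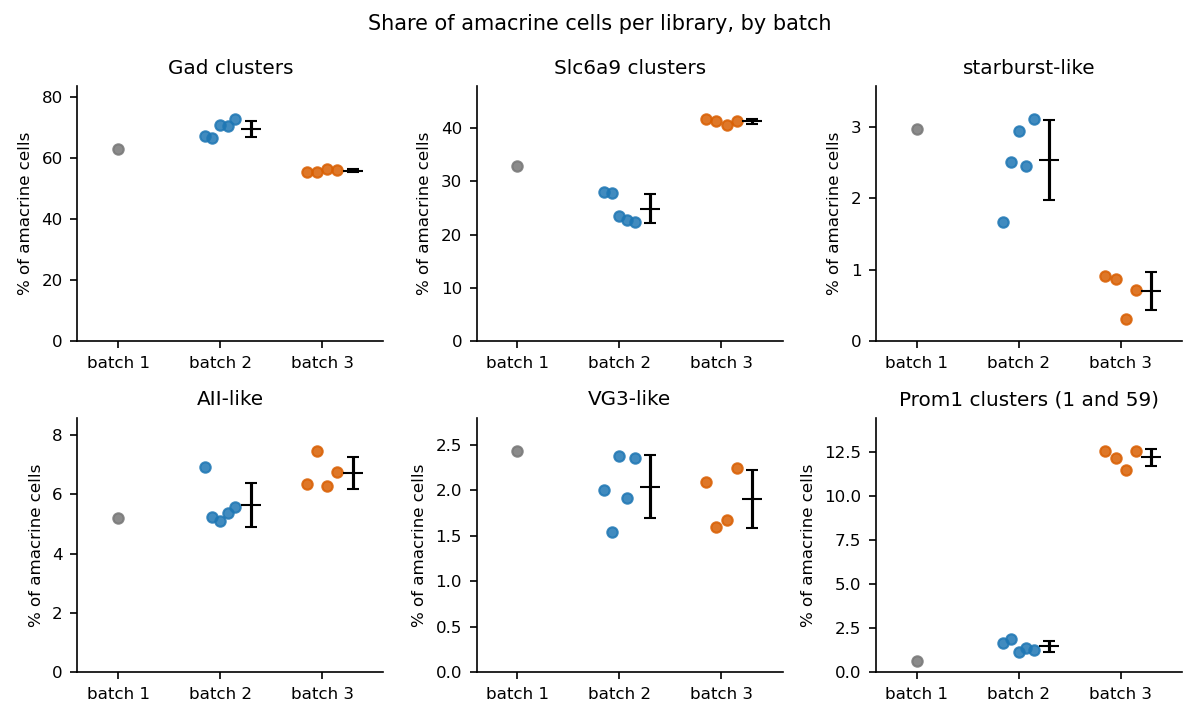
Share of amacrine cells (percent, vertical axes from 0) in 6 sets of clusters, with each point a library, grouped by batch; black bars give the mean ± SD of batches 2 and 3. Slc6a9 clusters lie at 24.9% ± 2.78 in batch 2 and 41.3% ± 0.442 in batch 3, while VG3-like cells overlap between these batches.

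The comparison of Slc6a9-gated with Gad-gated cells asked which genes part the glycinergic from the GABAergic class. Slc6a9-gated cells had more of the transcription factors Ebf1, Neurod2, Ebf3 and Tcf4, of the dopamine receptor Drd4 and of the connexin Gjd2, which forms electrical synapses. Gad-gated cells had more Meis2, Id4 and Maf, more of the GABA transporter Slc6a11, and more of most neuropeptides and adhesion molecules. Each gate pools many types, so a change can rest on a single type. Drd4, for example, had 327 ± 41.0 CPM in AII-like cells and 8.80 ± 2.65 CPM in all other amacrine cells. Slc32a1, the vesicular transporter that loads both GABA and glycine, was nearly level, at 610 ± 73.3 CPM in the Slc6a9 gate and 669 ± 53.5 CPM in the Gad gate (SD, n = 10). With 4509 Slc6a9-gated and 16191 Gad-gated cells, edgeR called 6861 of 11223 genes, 3557 higher and 3304 lower in the Slc6a9 gate. A change of at least 2-fold was found for 1450 of them, 552 higher and 898 lower. The balance of all calls turned in some alternatives, such as the test of DESeq2, with 3046 higher and 3169 lower. The gate itself set Gad1 (1236 ± 202 CPM in the Gad gate) and Slc6a9 (1507 ± 343 CPM in the Slc6a9 gate), which were not counted. Adjusted p-values from edgeR ranged from 1.73e-23 for Id4 to 1.29e-06 for Crhr1 over the list genes named in the next paragraphs, each of which moved in a single direction in all 10 libraries. The exception is Slc32a1, with a log2 change of -0.11 ± 0.03 (SE), an edgeR adjusted p of 0.00381 and a lower level in 9 of 10 libraries. Its call ended without the library block (adjusted p = 0.165 by edgeR) and in batch 3 alone (0.649).

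Transcription factors separated the classes in both directions. Of 67 tested, 28 were higher, 36 lower and 3 not called; 64 passed when adjusted over the list alone. Ebf1 was higher in the Slc6a9 gate by a log2 change of 5.05 ± 0.10 (SE), with 553 ± 61.4 CPM there. Neurod2, a bHLH factor of neuronal differentiation, was higher by 5.03 ± 0.08 and Ebf3 by 4.46 ± 0.22. Tcf4 (chromosome 18, 69343356 to 69689079, plus strand) was higher by 3.40 ± 0.04. Pou3f3 fell by 5.50 ± 0.26, Id4, an inhibitor of bHLH factors, by 5.28 ± 0.06 and Maf by 5.06 ± 0.15. Meis2 (chromosome 2, 115863064 to 116065839, minus strand) had 34.7 ± 13.7 CPM in the Slc6a9 gate and 804 ± 63.9 CPM in the Gad gate. As a set, the list did not lean in a single direction more than other genes (camera adjusted p = 0.0527). Camera does not see changes that go both ways. By at least 2-fold, 15 of the 67 were higher and 24 lower, against 552 and 898 of all 11223 genes tested.

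Neuropeptide genes were mostly lower in Slc6a9-gated cells. Of 16 tested, 3 were higher, 12 lower and 1 not called, and 15 passed when adjusted over the list alone; camera gave an adjusted p of 4.20e-05, and 0.0447 with an estimated correlation. Vip had 9.03 ± 5.49 CPM in the Slc6a9 gate and 422 ± 135 CPM in the Gad gate, Npy 19.1 ± 4.09 and 473 ± 59.8, and Tac2 11.7 ± 7.46 and 242 ± 35.6. Penk, the enkephalin precursor, went the other way, at 36.5 ± 9.19 against 4.41 ± 1.26 CPM. Of 11 neuropeptide receptors, 2 were higher, 7 lower and 2 not called (10 adjusted over the list alone). The somatostatin receptor Sstr2 fell by 3.57 ± 0.15 on the log2 scale and the receptor Crhr1 was higher by 1.81 ± 0.24. Camera gave this list an adjusted p of 0.00613, and its call was lost at an adjusted p of 0.298 with an estimated correlation.

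Among 19 other transmitter genes, 6 were higher, 11 lower and 2 not called (18 adjusted over the list alone; camera adjusted p = 0.117). The GABA transporter Slc6a11 fell by 4.29 ± 0.08 and the vesicular acetylcholine transporter Slc18a3 by 2.99 ± 0.22. Slc17a8 was higher by 4.68 ± 0.20 and Slc6a13, another GABA transporter, by 2.80 ± 0.13. Slc18a3 and Slc17a8 are naming markers of starburst-like and VG3-like cells. Of 25 glutamate receptor genes, 9 were higher, 14 lower and 2 not called (23 adjusted over the list alone). Grm7 fell by 1.33 ± 0.13, and the kainate receptor subunit Grik2 was higher by 1.16 ± 0.08. Of 19 GABA and glycine receptor genes, 7 were higher, 9 lower and 3 not called (16 adjusted over the list alone). The subunit Gabrg3 was higher by 2.60 ± 0.08 while Gabrd fell by 1.57 ± 0.09. This list's median log2 change was -0.09 and its mean 0.00, and camera placed it lower with an adjusted p of 0.604, against 0.491 for the glutamate receptors. Of 23 acetylcholine and monoamine receptors, 7 were higher, 12 lower and 4 not called (19 adjusted over the list alone; camera adjusted p = 0.491). Drd4 was higher by 4.68 ± 0.13 and the adrenergic receptor Adrb1 by 4.21 ± 0.11, whereas the adenosine receptor Adora1 fell by 3.65 ± 0.15.

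Channels, release proteins and adhesion molecules leaned to the Gad gate. Of 56 voltage-gated channel genes, 17 were higher, 29 lower and 10 not called (47 adjusted over the list alone). The potassium channel subunit Kcna6 fell by 3.48 ± 0.07 and the channel-interacting protein Kcnip1 fell by 4.25 ± 0.06, whereas the potassium channel Kcnh1 was higher by 3.56 ± 0.08. Camera gave an adjusted p of 0.00613, lost at an adjusted p of 0.190 with an estimated correlation. Of 41 synaptic release genes, 8 were higher, 27 lower and 6 not called (35 adjusted over the list alone). The synaptotagmin Syt7, a calcium sensor, fell by 2.85 ± 0.07, the active zone gene Rims1 by 2.83 ± 0.14, and the vesicle protein Sv2b was higher by 3.93 ± 0.13. Rims1 had 3966 ± 447 CPM in starburst-like cells and 37.3 ± 2.57 CPM in all other amacrine cells, so its change need not hold across the Gad class. The camera adjusted p of 0.000583 for this list became an adjusted p of 0.0526 with an estimated correlation. Of 76 recognition and adhesion genes, 18 were higher, 46 lower and 12 not called (66 adjusted over the list alone; camera adjusted p = 0.000259, and 0.0447 with an estimated correlation). Tenm3 fell by 3.62 ± 0.15 and Amigo2 by 3.08 ± 0.08, and Dscaml1 was higher by 2.90 ± 0.12. Of 21 calcium-binding genes, 12 were higher, 7 lower and 2 not called (19 adjusted over the list alone; camera adjusted p = 0.233). Calb1 (calbindin) had 378 ± 38.3 CPM in the Slc6a9 gate and 89.9 ± 10.1 CPM in the Gad gate, and Vsnl1 fell by 2.44 ± 0.04. Of 4 connexins and pannexins, Gjd2 was higher (3.01 ± 0.05), Gjc1 and 1 other were lower and 1 was not called (3 adjusted over the list alone); the median log2 change was -0.30, the mean 0.21, and camera placed the list higher with an adjusted p of 0.322. Outside the lists, Sct, the gene of secretin, was higher by 7.47 ± 0.15 and Slc6a12 by 6.46 ± 0.12, while Tnc fell by 6.01 ± 0.25 and C1ql2 by 5.75 ± 0.09.

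**Figure D2:**
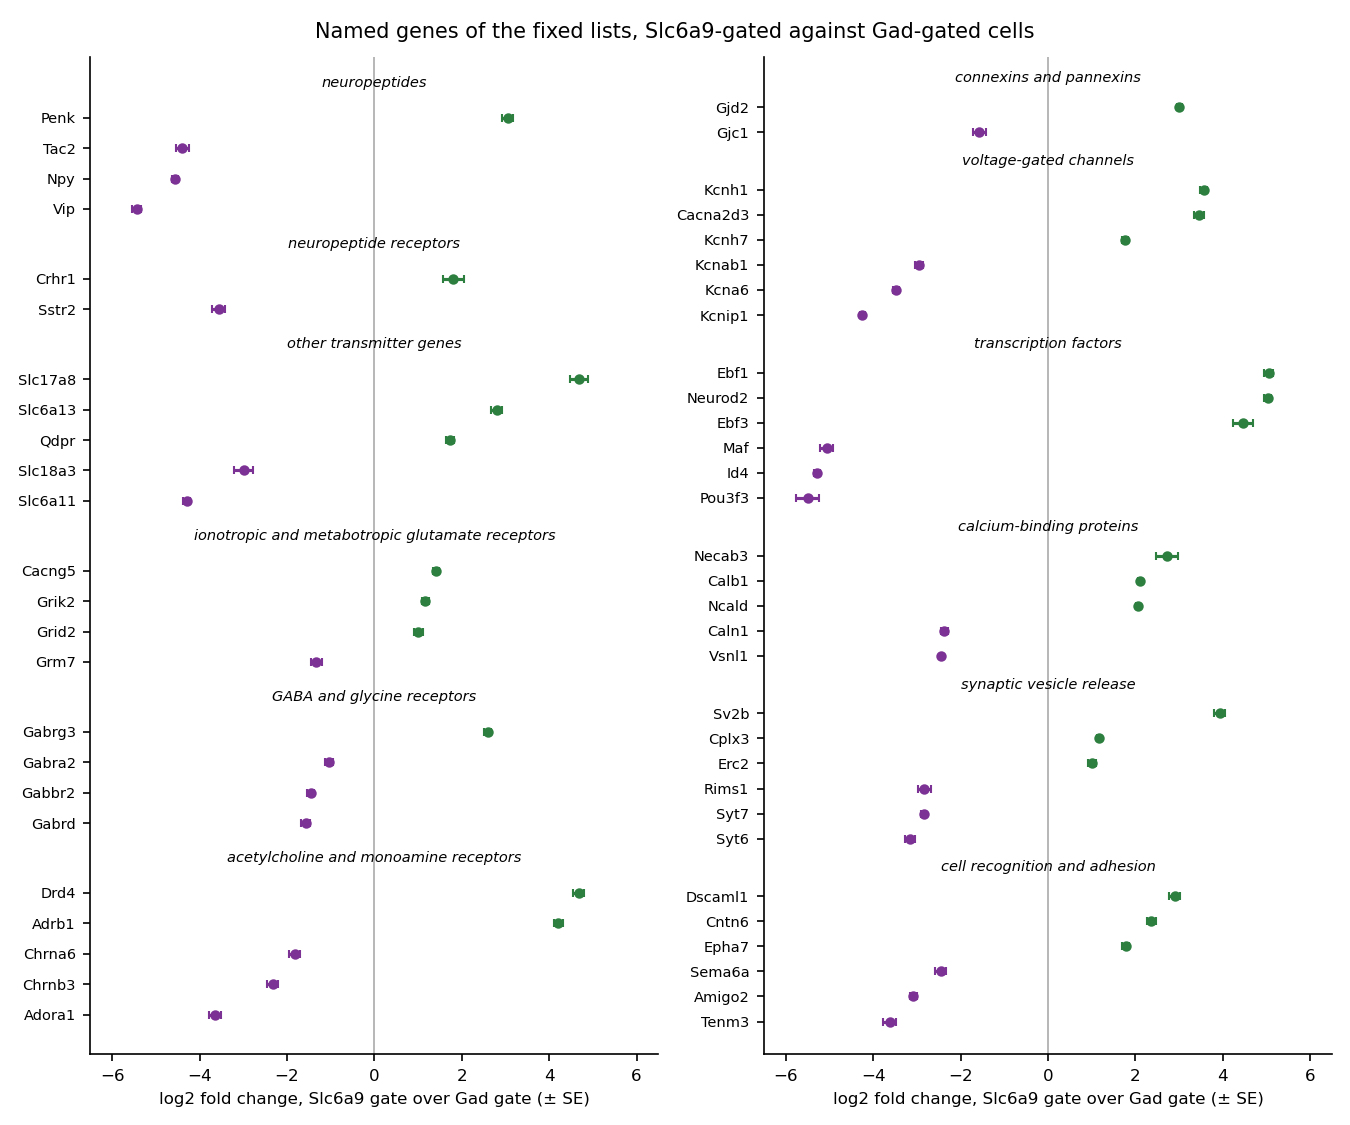
Log2 fold change (horizontal axes, Slc6a9 gate over Gad gate, 10 libraries) of genes of each fixed list, green where higher and purple where lower in Slc6a9-gated cells. Bars are the SE derived from the F statistic of edgeR. Ebf1 and Neurod2 reach 5.05 and 5.03, and the farthest on the lower side is Pou3f3 at -5.50.

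Starburst-like cells, the cholinergic amacrine type of direction-selective circuits, stood out by the active zone gene Rims1 (chromosome 1, 22286251 to 22805994, minus strand). It had 3966 ± 447 CPM there and 37.3 ± 2.57 CPM in all other amacrine cells (SD, n = 9 libraries with at least 10 such cells). The serotonin receptor Htr2b was higher by a log2 of 8.65 ± 0.24 (SE), at 71.5 ± 27.7 CPM against 0.177 ± 0.147, and the factor Fezf1 by 7.15 ± 0.33. Calretinin (Calb2) and Hpcal1 were higher by 3.91 ± 0.05 and 4.46 ± 0.06, and the adhesion gene Megf11 by 5.79 ± 0.09. Pomc (231 ± 31.3 CPM, log2 4.02 ± 0.09) and Pnoc, both precursors of opioid-system peptides, and the GABA receptor subunits Gabra4 and Gabrd (log2 3.96 ± 0.09 and 3.86 ± 0.06) were also higher. The metabotropic glutamate receptors Grm3 and Grm2 were higher by 3.78 ± 0.18 and 2.31 ± 0.13. EdgeR called 3831 of 9801 genes, 1944 higher and 1887 lower (1688 and 2235 with the size factors of DESeq2), and 408 were higher and 771 lower by at least 2-fold; the genes named here had edgeR adjusted p-values of at most 2.91e-22.

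By list, starburst-like cells had more genes lower than higher in every group except calcium-binding genes. Of 68 transcription factors 12 were higher and 47 lower, with 9 not called (62 called when adjusted over the list alone). Of 77 adhesion genes 20 were higher, 51 lower and 6 not called (72), and of 56 voltage-gated channels 13 were higher, 31 lower and 12 not called (46). Acetylcholine and monoamine receptors gave 4 higher, 17 lower and 2 not called of 23 (22), and neuropeptides 5, 10 and 3 of 18 (15). Neuropeptide receptors gave 1, 8 and 2 of 11 (10), glutamate receptors 7, 13 and 6 of 26 (21), and GABA and glycine receptors 7, 10 and 2 of 19 (17). For other transmitter genes the counts were 3, 11 and 3 of 17 (14), for synaptic release 13, 19 and 9 of 41 (33), and for connexins and pannexins 0, 2 and 2 of 4 (3). Calcium-binding genes leaned the other way, with 10 higher, 5 lower and 6 not called of 21 (15). In the 3 libraries of batch 3 with enough starburst-like cells alone, edgeR called 1335 genes.

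AII-like cells, the glycinergic type that passes rod signals to cone bipolar cells through gap junctions, had high Drd4 (chromosome 7, 141292006 to 141296464, plus strand). Its level was 327 ± 41.0 CPM against 8.80 ± 2.65 CPM in all other amacrine cells (SD, n = 10), and Adrb1 was higher by a log2 of 4.35 ± 0.09 (SE). Calb1 had 819 ± 95.9 against 98.5 ± 8.35 CPM. Kcnh1 was higher by 4.00 ± 0.08, Neurod2 by 2.77 ± 0.05 and Neurod4 by 2.66 ± 0.06, and the AMPA receptor subunit Gria3 by 1.22 ± 0.05. The NMDA receptor subunit Grin2a fell by 4.35 ± 0.17, Maf by 4.86 ± 0.16 and Kcnip1 by 4.13 ± 0.09. EdgeR called 5614 of 9783 genes, 2773 higher and 2841 lower, and 354 of these were higher and 1104 lower by at least 2-fold; the genes named here had edgeR adjusted p-values of at most 4.57e-30.

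The lists went mainly down in AII-like cells. None of 15 neuropeptides was higher and 14 were lower, with 1 not called (14 when adjusted over the list alone), and the counts of neuropeptide receptors were 0 higher, 9 lower and 1 not called of 10 (9). Of 75 adhesion genes 13 were higher, 59 lower and 3 not called (72), with Epha7 higher by 2.66 ± 0.07. Transcription factors gave 14, 49 and 4 of 67 (63), voltage-gated channels 15, 35 and 6 of 56 (50), and synaptic release 7, 27 and 7 of 41 (34). The release genes Cplx3 and Sv2b were higher by 1.57 ± 0.04 and 2.88 ± 0.07 while Syt7 fell by 3.61 ± 0.10. The remaining groups were glutamate receptors with 7, 15 and 3 of 25 (22), GABA and glycine receptors with 3, 12 and 4 of 19 (15), and acetylcholine and monoamine receptors with 3, 15 and 2 of 20 (18). Other transmitter genes gave 6, 11 and 2 of 19 (17), calcium-binding genes 4, 11 and 5 of 20 (15), and connexins and pannexins, without the marker Gjd2, 0, 2 and 1 of 3 (2).

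VG3-like cells, which carry a vesicular glutamate transporter, had Slc6a9 above its threshold (411 CPM) and Gad1 plus Gad2 below (445 CPM). They had the factor Lhx2 at 309 ± 61.2 CPM against 13.1 ± 2.56 CPM elsewhere (SD, n = 10). The neurotensin receptor Ntsr1 was higher by a log2 of 5.80 ± 0.26 (SE) and the VIP receptor Vipr2 by 2.31 ± 0.14. The serotonin receptors Htr1b and Htr1d were higher by 3.03 ± 0.19 and 2.77 ± 0.23. Gabra2 had 407 ± 48.3 against 93.7 ± 8.47 CPM, Grin2a 237 ± 37.3 against 53.8 ± 12.2 CPM, and Pcp4 9228 ± 2087 against 2230 ± 303 CPM. Calb2 fell by 2.20 ± 0.09, Gjd2 by 1.87 ± 0.17 and Tac2 by 3.88 ± 0.16. EdgeR called 2244 of 9807 genes, 930 higher and 1314 lower (172 and 328 by at least 2-fold), and adjusted p-values of the genes named here were at most 1.18e-12 except Gjd2 at 1.43e-11 (edgeR). In the 4 libraries of batch 3 alone it called 1406.

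In VG3-like cells, glutamate receptors were the list with more increases than decreases, 10 higher, 7 lower and 10 not called of 27 (17 when adjusted over the list alone). Neuropeptides gave 2, 11 and 4 of 17 (14), their receptors 2, 5 and 6 of 13 (7), and transcription factors 16, 37 and 16 of 69 (59). Adhesion genes gave 13, 38 and 26 of 77 (57), voltage-gated channels 17, 25 and 14 of 56 (47), and synaptic release 7, 17 and 17 of 41 (28). Acetylcholine and monoamine receptors gave 5, 14 and 4 of 23 (19), and GABA and glycine receptors 5, 6 and 8 of 19 (13). For other transmitter genes the counts were 1, 10 and 8 of 19 (15), for calcium-binding genes 5, 10 and 6 of 21 (15) and for connexins and pannexins 1, 2 and 1 of 4 (3).

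Most neuropeptide genes peaked in GABAergic clusters, some in a single cluster and others, such as Tac1, in several. Cartpt (chromosome 13, 99898489 to 99901091, minus strand) reached 56810 ± 7808 CPM in cluster 14 (SD, n = 10), against 110 CPM in the median cluster. Vip (chromosome 10, 5639218 to 5647617, plus strand) had 15862 ± 4650 CPM in cluster 25 and 3809 ± 801 CPM in cluster 27. Ghrh, the growth hormone releasing hormone, had 1322 ± 509 CPM in the 111 cells of cluster 64 (n = 9) and 23.2 ± 12.6 CPM in the next cluster, a mean log2 ratio of 5.34, higher in 9 of 9 libraries (exact sign-flip test, adjusted p = 0.00938). Tac2 led in cluster 43 with 5553 ± 953 CPM, which also led for Sst, and Tac1 in cluster 41 with 4039 ± 1099 CPM. Npy was shared, with 7436 ± 1084 CPM in cluster 36 and 6904 ± 1527 CPM in cluster 55, a difference within the spread between libraries (exact sign-flip adjusted p = 0.124). Cck, at 1448 ± 256 CPM, led in cluster 12, the only leading cluster of the Slc6a9 class, but cluster 34 of the Gad class was close at 1276 ± 492 CPM (exact sign-flip adjusted p = 0.145). Of 12 peptides tested, 9 had a leading cluster above the second (Vip, Sst, Penk, Tac1, Tac2, Crh, Grp, Ghrh and Pomc), and Npy, Cck and Pdyn did not pass. The leading cluster was chosen from the same libraries, so the direction was set by that choice and these p-values are too small. Under other clusterings or a minimum of 10 cells, Npy and Cck passed in some cases and Pomc, Sst and Tac1 failed in some. Sst was higher in 8 of 10 libraries, with 0 CPM in libraries 8 and 9, and the ratio of Tac1 turned to a log2 of -0.49 at Leiden resolution 5. Cartpt was not tested because its second cluster had enough cells in 5 libraries only. With at least 10 cells per library and cluster, the count of peptides that passed was 6.

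**Figure D3:**
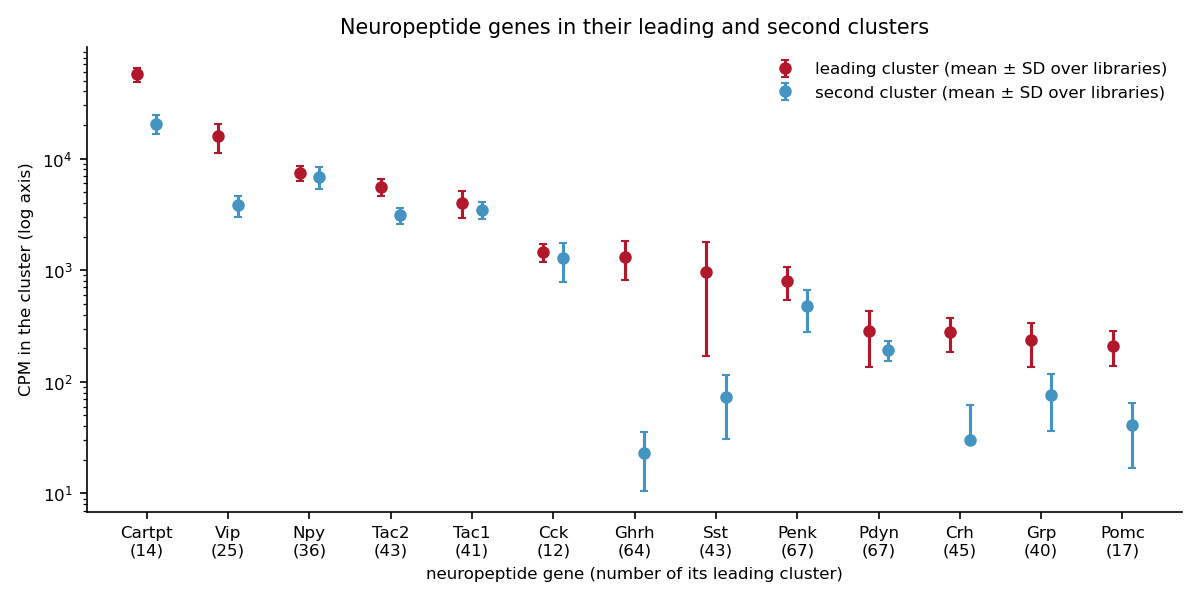
CPM (vertical log axis, mean ± SD over libraries) of the neuropeptide genes that reached 200 CPM, in the cluster with the highest level (red, number in brackets) and in the second (blue); no lower bar is drawn where the SD exceeds the mean. Ghrh shows the widest gap, and Npy and Cck lie at about the same level in both clusters.

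The batches differed in the shares of their clusters, and also in depth and in Malat1, a nuclear RNA. Median UMIs per cell were 3296.5 to 4284.5 in batch 2 and 4403 to 5598 in batch 3, and Malat1 took 6.33% to 7.21% and 5.09% to 5.51% of the UMIs, so a part of depth in the shares cannot be set aside. Slc6a9 clusters made up 24.9% ± 2.78 of the cells in batch 2 (n = 5) and 41.3% ± 0.442 in batch 3 (n = 4), and Gad clusters 69.6% ± 2.61 and 55.9% ± 0.479 (exact permutation p = 0.0159 for each, adjusted 0.0238 over 9 tests). Starburst-like cells were 2.53% ± 0.562 in batch 2 and 0.699% ± 0.272 in batch 3, with the same exact p. These calls, and those of the Prom1 clusters below, ended at an adjusted p of 0.0536 without any 1 of libraries 7 to 10, where the exact test can give no smaller p than 0.0357. Clusters 1 and 59, which held Slc6a9 and had Prom1 (chromosome 5, 43993620 to 44102032, minus strand) at 200 CPM or more, rose from 1.48% ± 0.316 to 12.2% ± 0.504, a ratio of 8.26 (exact p = 0.0159). Prom1 encodes CD133, against which the cells were sorted. Among the Gad clusters, 7, 9 and 23, with low UMI counts, fell from 4.73%, 3.76% and 2.43% in batch 2 to 0.457%, 0.997% and 0.194% in batch 3. Clusters 7 and 9 share leading genes, such as Bhlhe22 and Maf, with the deeper clusters 2 and 6, which rose from 3.70% and 2.73% to 5.54% and 4.19%. Cluster 23 shares Cxcl14 and Tmem114 with the deeper cluster 11, which rose from 2.04% to 2.82%. The falls in clusters 7, 9 and 23 were thus offset in part, and do not by themselves measure a loss of Gad cells. Cluster 9 had the highest Fos, a dissociation stress gene, of the amacrine clusters (2369 CPM), but Fos was also among the leading genes of cluster 6. Whether stress bears on these shares was not tested. AII-like cells (5.63% ± 0.742 and 6.70% ± 0.543, exact p = 0.0635) and VG3-like cells (2.04% ± 0.346 and 1.90% ± 0.317, exact p = 0.603) were not called, although the AII-like difference passed without library 2 (exact test, adjusted p = 0.0367). The AII-like total joins opposed shifts. Cluster 3 rose from 3.55% to 5.82%, while cluster 29, at 0.402 of the library median UMI count, fell from 1.91% to 0.715% (exact permutation p = 0.0159 for each). The single library of batch 1 had 32.9% Slc6a9 clusters and 0.636% Prom1 clusters. AII-marked clusters high for both transmitter genes (38, 60, 72 and 74), which the naming rule kept out of the AII-like class, made up 2.61% in batch 2 and 0.444% in batch 3. Their median UMI counts were 1.87 to 2.62 times the library median, and they are among the clusters that may hold doublets, as given below. If these clusters were counted as AII-like, the share of that type would be larger in batch 2, so the direction of its difference rests on the rule.

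Over all amacrine cells, edgeR called 7534 of 14065 genes between batch 3 and batch 2, of which 83 were higher and 174 lower by at least 2-fold. Prom1 had 72.2 ± 5.19 CPM in batch 3 and 17.9 ± 2.04 CPM in batch 2, and Spink13, also among the leading genes of cluster 1, 22.5 ± 0.695 and 4.66 ± 0.467. Other genes were far apart between these batches. Ltbp4 (log2 5.38 ± 0.07), U2af1l4 (4.64 ± 0.11) and Zfand4 (4.12 ± 0.05) were higher in batch 3, while Pcdhga8 fell by 9.65 ± 0.23, Smim20 by 8.21 ± 0.12, Nova2 by 7.83 ± 0.21, l7Rn6 by 6.26 ± 0.10 and AY036118 by 2.85 ± 0.26 (edgeR adjusted p of at most 1.22e-07). Apart from AY036118, these genes stand in an alphabetical block of 56 genes at the end of the matrix, and Pcdhga8 shares its last exons with the other genes of the gamma protocadherin cluster, so its counts are uncertain. Markers of dissociation stress, such as Fos and Jun, summed to 1704 ± 37.7 CPM in batch 2 and 1163 ± 32.4 CPM in batch 3 (exact p = 0.0159, adjusted 0.0688 over 13 lists). Every library of batch 2 lay above every library of batch 3, and 0.0159 is the smallest p this test can give, so the adjusted value is limited by the numbers of libraries and lists.

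Markers of other cell types stayed low in the amacrine cells. Summed CPM over 10 libraries was 71.7 ± 21.7 for rods, 115 ± 17.1 for cones, 116 ± 17.6 for bipolar cells and 21.9 ± 6.57 for microglia. It was 19.6 ± 1.28 for endothelium, 19.0 ± 5.13 for pericytes, 8.42 ± 3.62 for astrocytes and 1.27 ± 1.19 for erythrocytes. The pericyte sum was mostly Rgs5 (17.1 ± 4.79 CPM), which reached 1084 CPM in amacrine cluster 47. The lists of ganglion cells (532 ± 24.0), Müller glia (1105 ± 59.2) and horizontal cells (291 ± 7.54) were higher and include genes that amacrine clusters express, such as Nefl, at 1011 CPM in cluster 56. Bipolar markers summed to 129 ± 12.2 CPM in batch 2 and 98.2 ± 5.25 in batch 3, and Müller markers to 1068 ± 50.4 and 1159 ± 20.9 (exact p = 0.0159 for each, the smallest possible, adjusted 0.0688). The bipolar list includes Isl1, also a starburst marker, at 1000 CPM in cluster 17. Isl1 had 40.4 ± 6.61 CPM in batch 2 and 22.8 ± 4.02 CPM in batch 3, so part of the bipolar difference lay in a gene of starburst-like cells. The set-aside clusters held 2.06% ± 0.354 of the cells in batch 2 and 0.668% ± 0.269 in batch 3 (exact p = 0.0159).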

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

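The rule that looks for a library far from the others was applied to 41 quantities after they had been computed, and chance alone flags about 1 in 20 groups, so some of the 5 found are to be expected by chance. Library 1, the only library of batch 1, stood apart in 3 marker lists. Its rod markers, among them Sag, summed to 129 CPM against 50.8 to 82.3 CPM in the others, and its astrocyte markers to 18.2 CPM against 5.53 to 9.77 CPM. Its pan-amacrine markers, among them Pax6 and Tfap2b, were the lowest, at 4961 CPM against 5229 to 5463 CPM. Library 1 also had the fewest cells, 950, so its sums rest on the fewest UMIs.

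For 2 neuropeptides, a single library lay far from the others in the leading cluster. Grp, the gastrin releasing peptide, reached 489 CPM in library 8 and 141 to 316 CPM elsewhere. Pomc in starburst-like cells was 20.5 CPM in library 9 and 190 to 277 CPM in the others; library 9 held 5 starburst-like cells. The 515 cells with bipolar or Müller glia markers were in no comparison of genes, classes or types, and only their share was compared between batches. Clusters 52, 65 and 70 had Pcp2, a bipolar gene, at 411 to 837 CPM beside Gad1 at 217 to 1011 CPM, and cluster 61 had the glial genes Apoe at 1729 CPM and Glul at 1847 CPM. All had Slc32a1 at 381 to 557 CPM, and cluster 65 had Cartpt at 28295 CPM and cluster 70 Slc17a8 at 801 CPM. Median UMI counts were 3.55, 1.92 and 1.57 times the library median in clusters 52, 65 and 70 and 0.851 in cluster 61. Whether these are cells of other classes or doublets with amacrine cells was not tested. No biological explanation was tested for any of these values, since the labels give no group besides batch.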

How the results depend on the processing

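The alternatives without the 5% highest doublet scores, without the rows at the end of the matrix, and without each library for the shares were chosen after the results had been seen. Of 282 alternatives to the counts, shares and list tests, 245 were rated as unchanged. Counts were rated by a limit on their ratio to the main count, and mean shares by whether they moved less than the SD over libraries. Share differences and list tests were rated by direction and call. For named genes, 1924 of 1937 alternatives left the direction and the call as they were. Most of these genes had been named for a clear call in the main fit, so few could change and the tally says little about robustness. Both tallies include a run without the 25 cells that scrublet called, which could change little. The class comparison gave 5856 to 8034 genes, the AII comparison 4729 to 6375 and the batch comparison 6790 to 7550 (6790 to 7508 with each library left out). Batch 3 alone lowered the starburst count to 1335 and the VG3 count to 1406, with fewer libraries. Without the library block, edgeR called 5856 genes in the class, 3554 in the starburst, 5073 in the AII and 2006 in the VG3 comparison, and Slc32a1 lost its call (adjusted p = 0.165). Clusters high for neither transmitter held 5.16% of the cells when the class followed the share of cells with a UMI. That rule placed 3 clusters with 1515 cells there, against 1 cluster with 288 cells in the main rule. Slc6a9 clusters then numbered 14 with 8148 cells, against 17 with 9748. Clusters high for both numbered 10 with 1542 cells, against 9 with 1169. Gad clusters stayed at 46 with 20803 cells, so the cells gained by neither came from the Slc6a9 class.

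With each library left out, the difference of batch 3 from batch 2 in percentage points ranged from -14.5 to -13.0 for Gad clusters, 15.8 to 17.2 for Slc6a9 clusters and -2.76 to -2.25 for clusters high for both. It was -2.05 to -1.69 for starburst-like cells, 0.822 (without library 8) to 1.40 for AII-like cells, 10.6 to 11.0 for Prom1 clusters and -2.24 to -1.98 for AII-marked clusters with both transmitter genes. Without library 7, 8, 9 or 10 these were -13.6, -13.7, -14.0 and -13.9 for Gad, 16.3, 16.3, 16.6 and 16.4 for Slc6a9, and -2.57, -2.62, -2.42 and -2.50 for both. They were -1.90, -1.89, -1.70 and -1.84 for starburst-like cells, 10.6, 10.7, 11.0 and 10.6 for Prom1 clusters, and -2.22, -2.17, -2.12 and -2.14 for the AII-marked clusters. Each then lost its call at an adjusted p of 0.0536, because 3 libraries against 5 allow no exact p below 0.0357. Without library 2 the AII-like difference was 1.40 points and passed (exact test, adjusted p = 0.0367); the cause was not tested.

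Camera with an estimated correlation ended the calls of neuropeptide receptors (adjusted p = 0.298), voltage-gated channels (0.190) and synaptic release (0.0526). Fry, which asks whether the list moved at all instead of more than other genes, called other transmitter genes (adjusted p = 3.38e-07), glutamate receptors (0.000447), GABA and glycine receptors (0.0187), connexins and pannexins (4.20e-06), transcription factors (2.10e-05) and calcium-binding genes (5.29e-05). At resolution 5 the log2 ratio of Tac1 between its leading and second cluster reversed to -0.49; the cause was not tested. Npy passed with the lists among the features, at resolution 1.5 and at resolution 5 (log2 ratios 0.32, 1.38 and 0.35), and Cck at resolution 1.5 (1.07) and with 10 cells per cluster (0.41). Pomc failed with the lists among the features (1.05), Tac1 at resolution 1.5 (0.14) and with 10 cells (0.20), and Sst with 10 cells (2.39). Cacna1e in starburst-like cells lost its call in batch 3 alone (log2 -2.22), as did Slc32a1; the causes were not tested, and no other call changed. At a median of 4210 UMIs per cell, the gates held 64.7% of the amacrine cells, against 73.3% at 1 UMI and 50.4% at 4 UMIs. What part depth had in these shares was not tested.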

Other observations

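The tests named below were chosen after the results had been seen, except the tests of the CD133 sort and of doublets in the 8 clusters with both transmitter genes, whose predictions were written first. Some clusters outside the named types carried genes of other transmitter systems. Cluster 62 (130 cells) had Nos1, the neuronal nitric oxide synthase, at 623 CPM and the peptide gene Gal at 209 CPM, each the highest of all clusters. Cluster 20 (584 cells) combined Th at 209 CPM with Calb2 at 12059 CPM and Crhr2, a receptor of corticotropin releasing hormone peptides, at 169 CPM, while Ddc, the enzyme after Th in dopamine synthesis, had no count. Slc18a2, the vesicular monoamine transporter, peaked in cluster 53 at 120 CPM and not in cluster 20, where it had 10.7 CPM. Ebf3 was shared by clusters 26, 1 and 31 of the Slc6a9 class at 203, 200 and 198 CPM.

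The Prom1 clusters were 8.26 times as large a share in batch 3 as in batch 2, and the cells had been sorted against CD133, its product. A stricter sort in batch 2 was predicted to leave cells with less Prom1 there, but the ratio of Prom1 within the clusters was 1.004 (705 ± 70.5 and 708 ± 49.1 CPM, exact p = 0.952), which cannot tell whether the sort was the cause. Depth or cluster assignment alone is an unlikely cause, because the share of cells with at least 2 Prom1 UMIs after thinning to 2000 UMIs was 8.82 times higher in batch 3 (0.579% ± 0.122 and 5.10% ± 0.452, exact p = 0.0159) and 6.05 times as deposited; the thinning left out 23.8% of the amacrine cells of batch 2 and 12.2% of batch 3. In cells of Gad clusters the share with at least 2 Prom1 UMIs, as deposited, was also higher in batch 3 (0.297% ± 0.110 and 0.705% ± 0.194). Slc6a9 clusters without the Prom1 clusters still made up 23.8% ± 2.61 and 33.1% ± 0.196, so the Prom1 clusters do not account for all of the shift. No biological explanation was tested, since batch is the only group.

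Of 13 genes more than 16-fold apart between batches, 11 (84.6%) stood in the 56 alphabetical rows at the end of the matrix, of which 26 were tested. Neighbouring genes lay on 1 chromosome in 99.9% of cases before these positions and in 32.6% within them. A different mix of cell types is an unlikely cause, because the change within single clusters was 0.997 of that over all amacrine cells (median, 23 clusters). Whether counts of these genes, Rp1 of the rod markers among them, came from other gene records in 1 batch stays open, since that explanation was drawn from the same genes. No biological explanation was tested.

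The 8 clusters high for both Gad and Slc6a9 with more UMIs than the library median (997 cells) may hold doublets, because 34.3% of their cells were among the 5% highest doublet scores, against 4.36% in all other amacrine clusters. Their Meis2 (629 CPM) and Tcf4 (234 CPM) lay between the medians of Gad clusters (892 and 59.2 CPM) and Slc6a9 clusters (87.9 and 694 CPM). Cluster 57 (172 cells) was set apart by its median UMI count, 0.540 of the library median, so that value cannot tell whether it holds doublets, and the question stays open. It had 4.07% of its cells among the highest scores, Meis2 at 101 CPM, near the Slc6a9 clusters, Tcf4 at 41.6 CPM, near the Gad clusters, Gad1 at 3921 CPM, Slc6a9 at 216 CPM against at most 100 CPM in Gad clusters, and Rxfp3 and Chrna6 at 235 and 410 CPM. No biological explanation was tested.

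When sides or batches were reassigned at random, only the real assignment, 1 of 40 splits, reached its count in the class comparison (6861 genes, highest other 4388). The same held for starburst-like cells (1 of 40, 3831 against 405), AII-like cells (1 of 40, 5614 against 3404), VG3-like cells (1 of 40, 2244 against 874) and batches (1 of 100, 7534 against 4995). In the class and type comparisons the sides were defined by expression in these same cells. Their outcome was therefore set in advance and says nothing about chance. Only the batch comparison used groups given by the labels.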
